A study of Mus musculus with 8 samples.

How the data were processed

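Kidney RNA of mice was profiled by RNA-seq after ischemia-reperfusion (I/R), in which the blood supply of a kidney is stopped for a time and then restored. The series has 8 libraries: 4 carry the genotype label wild type and are called control 1 to 4 here, and 4 are labelled as myeloid FoxO1 knockouts and are called knockout 1 to 4. Per the labels' protocols, the knockout animals carried a tamoxifen-dependent Cre recombinase driven by Lyz2 together with floxed FoxO1, and tamoxifen was given at 75 mg per kg on 5 days. The right kidney was removed and the vessels of the left kidney were clamped for 35 minutes. The tissue was digested with collagenase before RNA extraction, and 1.3 µg of total RNA went into each library. The library kit named in the labels does not mark strand, so reads of a gene and of an antisense partner cannot be told apart. The tamoxifen dose is listed for all 8 samples, controls included, with no separate statement that the controls received it. The time from reperfusion to collection, and whether the controls carried Cre, are not given in the sources used here. Each library has its own number in its group, but no label says that the libraries came from separate animals. The p-values measure the spread between these libraries, which could be partly technical.

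The authors deposited 1 table of counts per gene with a column for each library and a gene length column. The counts are whole numbers with no normalization, and their totals differ between libraries. The submitters' processing notes name FastQC, Trim Galore 0.6.2, HISAT2 2.2.1, Salmon 1.10.2 and the mouse build mm39. Which of these produced the counts, the annotation and any filter are not given in the sources used here. Among values from 1 to 20, between 68.7% and 70.9% per library were even, against 49.5% to 50.4% among values over 100. Such an excess of even values arises when both mates of a read pair are counted, so a count here may stand for less than 1 independent fragment. The table also has an Ensembl identifier column, which did not match the gene symbols. Of 18423 identifiers known to the reference names, 13 (0.0706%) belonged to the symbol in the same line of the table. The deposited gene lengths had a rank correlation of 0.836 across genes with reference lengths looked up by symbol and of 0.0045 with lengths looked up by identifier. Genes were therefore taken by symbol and the identifiers were not used. The reference annotation at hand belongs to the assembly GRCm38.p6 and not to mm39, so no coordinates are given. It served only for transcript length, GC content and the order of neighbouring genes.

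Library totals ran from 29044405 counts (knockout 1) to 35530421 counts (control 3). The table has 25239 genes, of which 5807 had a total of 0 over the 8 libraries. No symbol of a mitochondrial gene was found in the table, and the haemoglobin genes stood at 0 in all 8 libraries. Counts of reads without molecular identifiers are not independent molecules, so the precision given by the depth covers counting error only; spread between libraries was taken from the replicates.

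The main test was edgeR 4.0.16 in R 4.3.3: filterByExpr by group with its minimum count of 10, TMM normalization, a quasi-likelihood fit (glmQLFit, glmQLFTest) of knockout against control over all 8 libraries with no covariate, and Benjamini-Hochberg adjustment over the 15000 genes tested. A gene was called changed at an adjusted p under 0.05. Fold changes are log2 of knockout over control, with standard errors (SE) derived from the F statistic. Levels are CPM, the usual scaling of counts by library size, with TMM factors, as mean ± SD over 4 libraries. Log2 CPM values used a prior count of 2.

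The 30 gene lists for cell types, pathways and possible contaminating tissues were fixed before the data were examined, as were the test, the rule for named genes and the settings to be varied. A list needed 3 measured genes. Adrenal genes had 2 measured genes, of which edgeR called 0 (0 at an unadjusted p under 0.05), and were not tested as a list, which left 29. Each list was tested with limma 3.58.1 camera at its preset correlation between genes of 0.01, with adjustment over the lists, and again with the correlation estimated from the data. Each list's mean log2 CPM per library was also compared by a two-sided exact permutation test over the 70 assignments of 4 against 4, whose smallest possible p is 0.0286. The direction counts of a list are given over all genes tested and, where stated, adjusted over the list alone.

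The rule for named genes had 3 parts. It took Foxo1, Lyz2, Adgre1, Havcr1, Lcn2 and Il1b always. It took the 8 highest and the 8 lowest fold changes among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, leaving out predicted genes and pseudogenes. It took up to 4 members, by smallest p, of each list past the camera threshold. Members outside these parts that are named to spell out a small count were chosen after their values were seen. Values of some genes that the rule or these counts take in are not reported here.

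The scripts were tested on simulated counts. In a simulation of knockout against control over 14831 genes with 200 changed genes, edgeR recovered 8.96% of the genes changed 1.5-fold, 49.3% of those changed 2-fold and 87.9% of those changed 4-fold, and 1.02% of its calls were false. In simulated lists without a change, 3 of 100 had a camera p under 0.05. Genes were simulated independently of each other, so this does not test camera on lists whose genes vary together. In the real lists the estimated correlation between genes reached 0.766 (oxidative phosphorylation genes). Libraries were compared before averaging: chi-square values per degree of freedom within groups ran from 22.4 to 195, so no 2 libraries matched within sampling noise.

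The settings varied were DESeq2 1.42.0, limma-voom with and without sample quality weights, other scalings (size factors, upper quartile, library totals), other low-count filters, the replicate number as a block, leaving out each library in turn, a surrogate variable from sva 3.50.0, a test against a 1.5-fold change, a looser threshold, and for the lists an estimated correlation, fry and the permutation test. After seeing the data, 4 were added: leaving out control 1 and knockout 3 (nearly no Lyz2 reads), leaving out control 2 and knockout 2 (highest Adipoq), leaving out Rn45s, and removing each library's trend with transcript length and GC content by splines with 4 degrees of freedom.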

Results

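The design asks how loss of the transcription factor FoxO1 from myeloid cells, which include macrophages, alters the kidney after I/R injury. The comparison has 4 control libraries and 4 libraries of the myeloid FoxO1 knockout, all from kidney after I/R, and no uninjured kidney was analysed here. The control libraries held 33143362, 33696974, 35530421 and 32627652 counts and the knockout libraries 29044405, 34738914, 34723754 and 31734946 counts. Between 16873 and 17285 genes were detected per library. The 10 most abundant genes took 9.72% to 11.4% of the counts, and the ribosomal RNA precursor Rn45s took 0.841% to 1.74%. The first principal component of the 500 most variable genes carried 58.9% of the variance and separated the groups: the controls lay between -45.1 and -10.98 and the knockouts between 21.5 and 28.3. Control 1 lay farthest out. Pearson correlations of log2 CPM across genes were 0.954 to 0.981 between controls, 0.969 to 0.985 between knockouts and 0.912 to 0.966 between the groups.

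**Figure D1:**
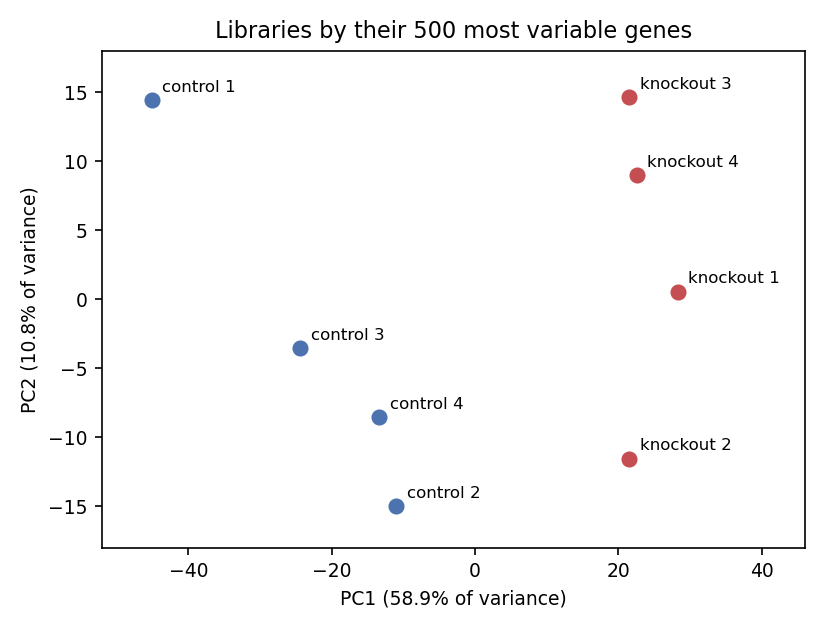
Principal components of log2 CPM of the 500 most variable genes, 1 point per library, controls in blue and knockouts in red. The first component, with 58.9% of the variance, separates the groups, and control 1 lies at -45.1.

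Foxo1, the targeted gene, stood at 34.5, 33.4, 33.0 and 33.9 CPM in controls 1 to 4 and at 41.4, 41.0, 42.9 and 39.3 CPM in knockouts 1 to 4. The means were 33.7 ± 0.626 CPM and 41.1 ± 1.49 CPM (SD, n = 4 each), a log2 fold change of 0.29 (SE 0.09) that did not pass the threshold (edgeR adjusted p = 0.0647). The 2 groups did not overlap. These are levels of whole kidney tissue, in which other cells also express Foxo1, and counts per gene do not tell a deleted allele from an intact one. The value therefore does not check the knockout in myeloid cells. The same value passed the threshold in DESeq2 (adjusted p = 0.0195), with sample quality weights (0.0453) and with a surrogate variable (0.0249); over 24 alternatives its adjusted p ran from 0.0195 to 1.00.

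Lyz2, the lysozyme gene of myeloid cells that drives the Cre recombinase, varied within both groups. Control 1 had 81 counts of Lyz2 against 844 to 1610 in the other controls, and knockout 3 had 13 against 858 to 1302 in the other knockouts. Between the groups Lyz2 had a log2 fold change of -0.18 (SE 0.98, edgeR adjusted p = 0.925), and its direction turned when control 2 (0.26) or knockout 3 (0.23) was left out. Adgre1, which encodes the macrophage surface protein F4/80, stood at 7.08 ± 2.09 CPM in controls and 8.66 ± 1.43 CPM in knockouts (log2 fold change 0.29, SE 0.23, adjusted p = 0.454). Reads of Lyz2 can be shared with its close paralog Lyz1, which had 12 to 183 counts per library.

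**Figure D2:**
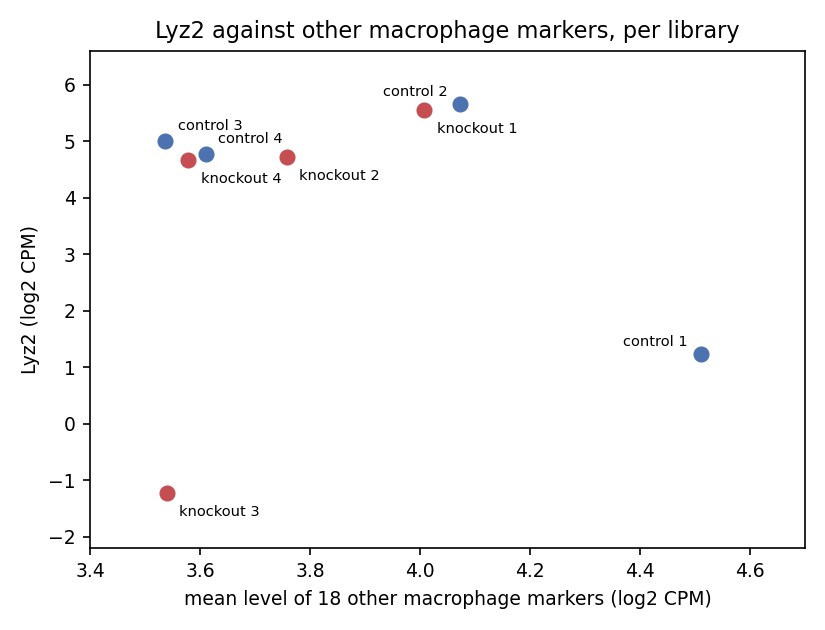
Lyz2 in log2 CPM (vertical axis) against the mean log2 CPM of 18 other macrophage and monocyte markers (horizontal axis), 1 point per library, controls in blue and knockouts in red. Control 1 and knockout 3 lie at 1.22 and -1.23 for Lyz2, below the other 6 libraries, and control 1 has the highest level of the other markers, at 4.51.

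Across the tissue, 1909 of 15000 genes changed, 967 higher and 942 lower in the knockout, and 815 of them changed at least 2-fold (489 higher, 326 lower). Among the highest were Slc7a12, a transporter-family gene, at 0.738 ± 0.713 CPM in controls and 37.0 ± 2.31 CPM in knockouts, and the aldo-keto reductases Akr1c18 (6.67 ± 7.02 and 190 ± 108 CPM) and Akr1c14 (9.46 ± 4.54 and 112 ± 22.7 CPM, 11.8-fold higher). Uroc1, an enzyme of histidine breakdown, Sec14l3 and Nccrp1 rose 14.9-fold, 11.9-fold and 10.9-fold. Kcna1, a potassium channel, and Scgb1c1, a secretoglobin, had 0 to 9 counts per control library, so only their knockout levels of 9.69 ± 4.31 and 8.47 ± 4.71 CPM are given (SD, n = 4 each). The lowest were Vgf, a secreted neuropeptide precursor, at 38.0 ± 27.98 CPM in controls and 0.688 ± 0.469 CPM in knockouts, Crct1 (6.16 ± 2.72 and 0.125 ± 0.113 CPM), the neutrophil genes Retnlg and Cxcr2, Krt20, Prss22 (10.1-fold lower), Grp, which encodes gastrin-releasing peptide (9.28-fold lower), and Plin2, a lipid droplet coat protein that went from 1501 ± 609 to 167 ± 30.1 CPM (8.99-fold lower).

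The counts are those of edgeR at an adjusted p under 0.05; 4368 genes had an unadjusted p under 0.05, and 3255 genes (21.7%) had groups that did not overlap, against 2.86% expected by chance. The count fell to 1058, 1050, 1139 and 907 without control 3, knockout 2, knockout 3 and knockout 4, and to 1045 without control 1 and knockout 3 together and 1008 without control 2 and knockout 2 together. With length and GC trends removed, 39.2% of 2738 calls were higher, against 50.7% here. Single libraries moved some folds by more than 1.5 times: without control 2 the log2 fold change was 5.09 for Nccrp1 (against 3.45) and 5.84 for Akr1c18 (against 4.83), without control 3 it was 6.51 for Slc7a12 (against 5.63), and without knockout 4 it was -4.18 for Prss22 (against -3.33). Akr1c genes are close paralogs and may share reads, and the call of Nccrp1 was lost in 5 of the 8 fits that left out 1 library (without control 3, control 4, knockout 1, knockout 2 or knockout 4, adjusted p up to 0.0702).

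**Figure D3:**
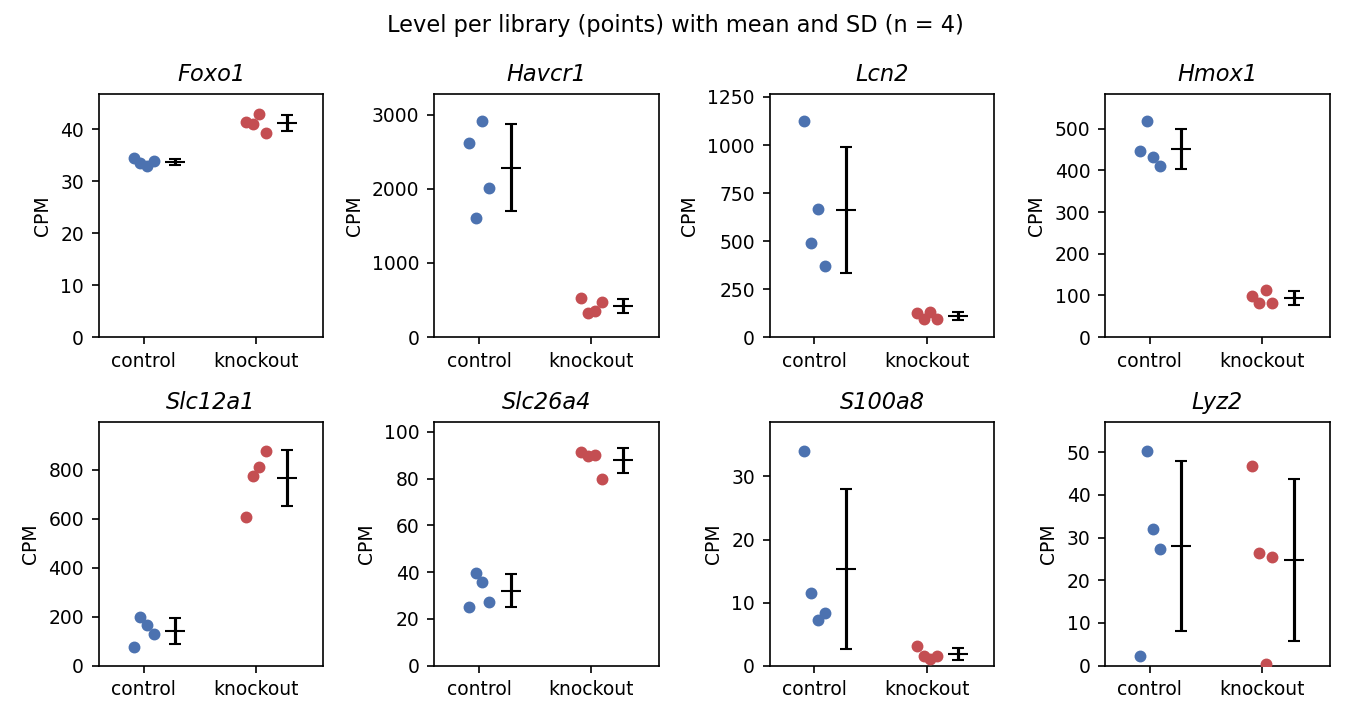
Levels of 8 named genes in CPM, 1 point per library, with the mean and SD of each group (n = 4) beside the points. Havcr1, Lcn2, Hmox1 and S100a8 are lower in all 4 knockouts than in all 4 controls, Slc12a1, Slc26a4 and Foxo1 are higher in all 4 (for Foxo1, adjusted p = 0.0647), and the groups overlap for Lyz2.

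Genes of injured tubule cells were lower in the knockout. Of 22 measured, 19 fell, 0 rose and 3 did not pass (20 fell when adjusted over the list alone). Havcr1, which encodes the injury marker KIM-1, fell from 2286 ± 590 CPM in controls to 419 ± 92.2 CPM in knockouts (5.45-fold lower, log2 fold change -2.45, SE 0.23, edgeR adjusted p = 5.80e-04). Lcn2, which encodes the injury marker NGAL, fell from 663 ± 329 to 111 ± 19.6 CPM (5.98-fold lower), and Krt20, an epithelial keratin, from 277 ± 143 to 24.6 ± 5.70 CPM (11.3-fold lower). Krt8 and Anxa2 fell 3.38-fold each. Vcam1, Anxa1 and Krt19 did not pass, with log2 fold changes of 0.01, -0.65 and -1.01. Read sharing in the Sprr family leaves Sprr1a and Sprr2f uncertain. The mean log2 level of the list differed by -1.82, knockout minus control (exact permutation p = 0.0286, adjusted 0.0829 over the lists), and its camera adjusted p was 2.14e-16. With an estimated correlation the adjusted p = 0.121. The immediate early and heat shock genes had been listed as a sign of sample handling. Their level differed by -0.63 between the same groups (knockout minus control, exact permutation p = 0.0286). Whether handling or the injury itself moved these genes was not tested.

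Markers of the loop of Henle and of the distal nephron were higher in the knockout. In the loop of Henle, the segment that makes the urine-concentrating gradient, 9 of 11 measured markers rose and 0 fell (10 rose when adjusted over the list alone). Slc12a1, the sodium-potassium-chloride cotransporter NKCC2, rose from 142 ± 52.4 to 766 ± 115 CPM (5.39-fold higher, log2 fold change 2.43, SE 0.27, edgeR adjusted p = 0.00110). The potassium channel gene Kcnj1 and the prostaglandin receptor gene Ptger3 rose 2.78-fold and 2.35-fold. In the distal nephron and collecting duct 13 of 16 rose and 0 fell (15 rose when adjusted over the list alone), among them Slc4a1, an anion exchanger of intercalated cells (5.65-fold), the water channel gene Aqp3 (2.96-fold), Slc26a4, which encodes pendrin (2.75-fold), and the sodium channel subunit gene Scnn1b (1.88-fold). The camera adjusted p was 2.69e-09 for the loop of Henle and 1.44e-09 for the distal list; with an estimated correlation the adjusted p = 0.236 for both. The immediate early and heat shock genes named above, at -0.63, separated the same groups.

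Of 22 proximal tubule markers measured, 4 rose, 1 fell and 17 did not pass (the same counts when adjusted over the list alone), with a median log2 fold change of 0.31. Slc7a13, an amino acid transporter gene, rose 3.10-fold (log2 fold change 1.63, SE 0.18), Slc5a8 rose 2.30-fold and Lrp2, which encodes the endocytic receptor megalin, 1.99-fold. Miox, an inositol oxygenase, was the other gene that rose. Cyp4b1 fell 1.96-fold (log2 fold change -0.97, SE 0.22). Related Slc22 transporters in this list may share reads. In camera the list had an adjusted p of 0.0111, and adjusted p = 0.721 with an estimated correlation, and its mean level had an exact permutation p = 0.143. The list's call was lost without control 1 (adjusted p = 0.0900) and without control 1 and knockout 3 together (0.246). The count of risen genes was 2 without control 3, knockout 2, knockout 3 or knockout 4, where Lrp2 lost its call (adjusted p up to 0.0666), and Cyp4b1 lost its call without knockout 4 (0.0538).

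Podocyte and endothelial markers were compared next. In podocytes, the filter cells of the glomerulus, 5 of 9 measured markers rose and 0 fell (6 rose when adjusted over the list alone): Podxl 1.48-fold, Synpo 1.42-fold, Nphs1, which encodes nephrin, 1.42-fold, Tcf21 2.71-fold, and Wt1. Of 14 endothelial markers 3 rose and 0 fell, in both adjustments: Tek 2.09-fold, Kdr, which encodes VEGF receptor 2, 1.78-fold, and Ptprb 1.83-fold. Ehd3 had a log2 fold change of 0.69 (edgeR adjusted p = 0.122). The camera adjusted p was 1.82e-04 for podocytes and 0.00325 for endothelium; with an estimated correlation the adjusted p = 0.236 and adjusted p = 0.719. Podocyte markers differed by 0.65 in mean log2 level (knockout minus control, exact permutation p = 0.0286, against 0.0571 for the endothelial level), where the immediate early and heat shock genes differed by -0.63 and the injured tubule genes by -1.82. The podocyte count fell to 1 without control 3 or knockout 4, to 2 without control 4 or knockout 2 and to 3 without control 1 or knockout 3, and the endothelial count fell to 0 without knockout 3 or knockout 4 and to 1 without control 3.

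Among nuclear genes of oxidative phosphorylation, the mitochondrial pathway that makes most ATP, 1 of 22 measured rose and 0 fell (0 rose when adjusted over the list alone), with a median log2 fold change of 0.29. Sdhb, a subunit of complex II, rose 1.52-fold, from 285 ± 52.4 to 433 ± 57.8 CPM. Ndufs1, Atp5a1 and Sdha had log2 fold changes of 0.42, 0.43 and 0.38 and did not pass (edgeR adjusted p = 0.0572, 0.0912 and 0.103). For the list, the camera adjusted p was 0.00119, with an adjusted p = 0.721 with an estimated correlation and an exact permutation p = 0.143 for its mean level. Sdhb lost its call in 6 of the 8 fits that left out 1 library (adjusted p up to 0.0999, without knockout 2), which left 0 called genes without control 1, control 3 or any 1 knockout. DESeq2 called 4 of the 22 as risen.

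Of 18 genes of cholesterol synthesis measured, 9 rose, 0 fell and 9 did not pass (11 risen and 1 fallen when adjusted over the list alone). Cyp51, which removes a methyl group from lanosterol, rose from 110 ± 40.0 to 315 ± 87.5 CPM (2.85-fold, edgeR adjusted p = 0.00862). Nsdhl rose 1.79-fold and Msmo1 1.58-fold. In camera the adjusted p was 1.17e-05, with an adjusted p = 0.462 with an estimated correlation. Over the same groups the mean log2 level differed by 0.68 for this list, by -0.63 for the immediate early and heat shock genes, by -1.82 for the injured tubule genes and by 1.45 for the loop of Henle markers (knockout minus control, exact permutation p = 0.0286 each). The count of risen genes was 5 without control 3, 6 without knockout 1 or knockout 3 and 4 without knockout 2 or knockout 4.

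Of 18 genes of regulated cell death 8 fell, 0 rose and 10 did not pass (12 fell when adjusted over the list alone), among them the TNF receptor gene Tnfrsf1a (1.65-fold lower), Casp8, an initiator caspase (1.73-fold lower), the p53 target Phlda3 (1.61-fold lower) and the death receptor gene Tnfrsf10b (2.52-fold lower). Of 18 genes regulated by the oxidative stress factor NRF2 or acting as antioxidants, 7 fell, 0 rose and 11 did not pass (9 fell and 1, Sod2, rose when adjusted over the list alone). Hmox1, which encodes heme oxygenase 1, fell from 452 ± 47.4 to 93.9 ± 15.7 CPM (4.81-fold lower, log2 fold change -2.27, SE 0.15, edgeR adjusted p = 1.77e-04), Srxn1 fell 2.80-fold, Txnrd1 1.88-fold and Slc7a11, the cystine transporter gene, from 4.92 ± 5.71 to 0.568 ± 0.276 CPM. Immediate early and heat shock genes were taken as a sign of sample handling, since they can respond to tissue digestion, which the protocol includes. Whether handling or the injury itself set their level was not tested. Of 16 measured, 7 fell, 0 rose and 9 did not pass (9 fell when adjusted over the list alone), and their mean log2 CPM ran from 5.62 to 5.99 in controls and from 5.04 to 5.16 in knockouts. The 7 that fell were immediate early genes, including Junb (2.75-fold lower), Jun (2.43-fold lower), Egr1 (2.25-fold lower) and Btg2 (1.82-fold lower). None of the heat shock genes passed the threshold; Hspa1a and Hspa1b are near-identical copies and their split of reads is uncertain.

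The camera adjusted p was 5.14e-06 for cell death, 5.14e-06 for immediate early and heat shock genes and 0.0129 for the NRF2 list. With an estimated correlation the adjusted p = 0.121, adjusted p = 0.121 and adjusted p = 0.369. The NRF2 list lost its camera call without control 4 (adjusted p = 0.0655), its count of fallen genes was 3 without knockout 3 or knockout 4 and 4 without control 3 or knockout 2, and Slc7a11 lost its call without knockout 2, 3 or 4 (adjusted p up to 0.0799). Without control 1 the log2 fold change of Slc7a11 was -1.89, against -3.13. The cell death count was 5 without knockout 2 or knockout 4.

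Of 22 cell cycle genes measured, 2 fell, 0 rose and 20 did not pass (1 fell when adjusted over the list alone), with a median log2 fold change of -0.42. Mcm2, a subunit of the replicative helicase, fell 1.39-fold and Pcna, the sliding clamp of DNA replication, 1.34-fold. Tpx2 and Mcm3 had log2 fold changes of -1.06 and -0.65 and did not pass (edgeR adjusted p = 0.0838 and 0.110). The camera adjusted p was 0.00213, with an adjusted p = 0.719 with an estimated correlation and an exact permutation p = 0.143 for the mean level of the list. Its camera call was lost without control 2 and knockout 2 together (adjusted p = 0.109). Pcna lost its call in each of the 8 fits that left out 1 library (adjusted p up to 0.125, without knockout 3) and Mcm2 without control 4, knockout 2, knockout 3 or knockout 4 (up to 0.0853). The count of fallen genes was 0 in those 4 fits, 1 without control 1, 2 or 3 and 3 without knockout 1.

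Neutrophil markers were lower in the knockout. Of 8 measured, 6 fell and 0 rose, in both adjustments. S100a8, an abundant neutrophil calcium-binding protein gene, fell from 15.3 ± 12.7 to 1.83 ± 0.898 CPM (8.43-fold lower, log2 fold change -3.08, SE 0.55, edgeR adjusted p = 0.00749), Retnlg fell 12.7-fold, the chemokine receptor gene Cxcr2 9.10-fold and Csf3r 6.81-fold. S100a9 fell 6.77-fold and Il1r2 was the other gene that fell. In the knockout libraries Retnlg had 0 to 26 counts and Cxcr2 4 to 26, so the sizes of their folds are uncertain. Control 1 had the highest level of S100a8 (34.1 CPM, against 7.19 to 11.5 CPM in the other controls and 1.07 to 3.13 CPM in the knockouts). The camera adjusted p was 0.00213, with an adjusted p = 0.539 with an estimated correlation. Without control 1 the log2 fold changes were -2.31 for S100a8, -2.78 for Retnlg (against -3.66), -2.10 for Cxcr2 (against -3.19), -1.61 for Csf3r (against -2.77) and -2.03 for S100a9 (against -2.76), and the list median was -1.85 (against -2.92). Without knockout 1, Retnlg was at -4.37. In the same groups the injured tubule level differed by -1.82 and the level of immediate early and heat shock genes by -0.63. The count of fallen markers was 6 without any 1 control, and 4, 1, 3 and 2 without knockout 1, 2, 3 and 4. That count was 4 in DESeq2, 4 with the replicate block and 4 without control 1 and knockout 3 together.

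Inflammatory cytokines and chemokines fell in 2 of 16 measured genes and rose in 0 (6 fell when adjusted over the list alone). DESeq2 called 8 of 20 measured as fallen, and limma-voom with sample quality weights 4 of 16. Cxcl1, a chemokine that attracts neutrophils, fell from 14.6 ± 8.70 to 3.06 ± 1.00 CPM (4.77-fold lower) and Icam1, an adhesion molecule of leukocyte entry, from 70.2 ± 14.1 to 41.8 ± 3.44 CPM (1.68-fold lower). Il1b, which encodes interleukin 1 beta, stood at 4.84 ± 3.45 CPM in controls and 1.92 ± 0.774 CPM in knockouts (log2 fold change -1.33, SE 0.47, edgeR adjusted p = 0.0873), and Ptgs2 had a log2 fold change of -2.19 (adjusted p = 0.0632). Without control 1 their log2 fold changes were -0.70 and -1.38 (adjusted p = 0.222 and 0.174), and both passed in DESeq2 (adjusted p = 0.0244 and 0.00756). For the list, the camera adjusted p was 0.0129, with an adjusted p = 0.401 with an estimated correlation and an exact permutation p = 0.0571 for its mean level. The mean log2 level of the neutrophil markers differed by -2.02 between the same groups (knockout minus control, exact permutation p = 0.0286), and that of the injured tubule genes by -1.82.

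Markers of macrophages and monocytes went both ways. Of 20 measured, 1 rose (Mertk, a receptor for dead cells) and 3 fell (Ccr2, Cd14 and Itgam), with 2 risen and 4 fallen when adjusted over the list alone. The median log2 fold change was -0.03, the mean -0.34 and the camera adjusted p 0.841. The count of fallen markers was 1 without any 1 knockout, and the count of risen markers was 0 without control 3, knockout 2, knockout 3 or knockout 4 and 2 without control 1 or control 2. DESeq2 called 2 risen and 5 fallen. Cd14 fell from 106 ± 26.8 to 30.0 ± 6.80 CPM and Mertk had a log2 fold change of 0.61 (SE 0.15). Among genes of alternatively activated macrophages 2 of 13 fell and 0 rose (7 fell when adjusted over the list alone): Arg1, which encodes arginase 1, from 15.3 ± 16.7 to 1.84 ± 0.757 CPM, and Chil3 from 24.4 ± 32.9 to 3.55 ± 0.940 CPM, with a camera adjusted p of 0.0586 (0.0110 without control 3 and 0.0309 without control 4). Of that list, edgeR called 0 genes as fallen without knockout 1, 2 or 4 and 1 without knockout 3 or control 3. With all 8 libraries, 7 members had an unadjusted p under 0.05, and DESeq2 called 7 of 15 as fallen. Control 1 had the highest mean log2 CPM of that list, at 3.00, against 1.86 to 2.45 in the other controls. The mean log2 level of that list differed by -0.76, knockout minus control (exact permutation p = 0.0286, adjusted 0.0829 over the lists). In camera with an estimated correlation its adjusted p = 0.670. Among efferocytosis genes, which act in the removal of dead cells, 1 of 15 rose (Mertk, which was not called without control 1, control 3, knockout 2, knockout 3 or knockout 4) and 1 fell (Cd36), with 2 in each direction when adjusted over the list alone, a median log2 fold change of 0.02, a mean of -0.04 and a camera adjusted p of 0.998. Without control 2, 2 efferocytosis genes fell, and without control 4, 2 rose. None of 9 T and NK cell markers and none of 4 B and plasma cell markers passed in edgeR (camera adjusted p = 0.103 and 0.998), with 2 and 0 members at an unadjusted p under 0.05; 1 of the T and NK markers rose in DESeq2 and 1 in edgeR without control 4. The T and NK list passed in camera without control 2, control 4 or knockout 3 (adjusted p = 0.0284, 0.0391 and 0.0412).

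Of 22 FoxO target genes measured, 3 rose (Sesn1, Trim63 and Igfbp1), 2 fell (Pdk4 and Gadd45a) and 17 did not pass, with 3 risen and 3 fallen when adjusted over the list alone. The median log2 fold change was 0.09, the mean -0.05 and the camera adjusted p 0.998. Pdk4, a kinase that restrains glucose oxidation, fell from 89.0 ± 42.8 to 20.5 ± 5.35 CPM. These target genes were measured in whole tissue. The count of risen targets was 0 without control 3, knockout 1, knockout 2 or knockout 4, 1 without control 1 and 2 without control 2, control 4 or knockout 3. The count of fallen targets was 4 without control 3, 3 without control 2 or knockout 1 and 2 in the other 5 of these fits, and DESeq2 called 3 risen and 6 fallen of 24.

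In the other lists at most 4 genes passed in each direction in edgeR. Of 20 fibroblast and matrix genes 1 rose (Mmp2) and 3 fell, among them Tnc and Tgfbi. Of 20 fatty acid oxidation genes 2 rose (Acat1 and Ppargc1a) and 1 fell (Pdk4). Of 20 glycolysis and hypoxia genes 2 rose (Hk1 and Pdk1) and 2 fell (Hk2 and Adm). Of 23 interferon response genes 1 rose (Rsad2) and 1 fell (Ly6e). Of 14 complement genes 2 rose (C1s1 and Serping1) and 1 fell (C5ar1), and of 16 endoplasmic reticulum stress genes 4 fell (Chac1, Asns, Ddit3 and Dnajb9). Their camera adjusted p values were 0.590, 0.301, 0.590, 0.104, 0.998 and 0.290 in that order. Adjusted over the list alone, the risen and fallen counts were 3 and 4, 4 and 1, 3 and 2, 1 and 1, 4 and 1, and 1 and 6. In DESeq2 they were 3 and 4, 4 and 1, 3 and 2, 3 and 1, 4 and 1, and 0 and 6. Without knockout 4 the risen and fallen counts were 0 and 2, 1 and 1, 1 and 2, 0 and 0, 0 and 0, and 0 and 1, and each of the other 7 libraries, when left out, also moved at least 1 of these counts by more than 1.5 times. The interferon list passed in camera without control 2 or knockout 2 (adjusted p = 0.0137 and 0.00876). The complement list had a median log2 fold change of -0.22 and a mean of 0.01.

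Genes of other tissues were checked as well, and Y-linked genes as a check of sample identity. None of 3 erythroid genes, 7 adipocyte genes or 4 Y-linked genes passed in edgeR (camera adjusted p = 0.998, 0.103 and 0.403), nor did any when adjusted over the list alone, and 1, 0 and 1 of them had an unadjusted p under 0.05. In DESeq2 1 erythroid gene rose and 1 adipocyte gene fell. The erythroid genes had a median log2 fold change of -0.03 and a mean of 0.21. Only 3 of the 9 members of the erythroid list were measured. Its haemoglobin genes stood at 0 in every library, so the list could say little about blood. The mean log2 CPM of the Y-linked genes ran from 3.38 to 4.07 over the libraries, and Xist had 0 to 8 counts per library. The adipocyte hormone gene Adipoq was at 8.39 CPM in control 2, 4.69 CPM in control 3 and 8.60 CPM in knockout 2, and between 0 and 1.69 CPM in the other 5 libraries. Plin1, of the same list, ran from 3.34 to 9.98 CPM in controls. It was at 7.76 CPM in knockout 2 and at 0.072 to 0.326 CPM in the other knockouts. Cidec in knockout 1 (4.64 CPM) and Car3 in knockout 3 (13.7 CPM) lay within the range of the controls. All 7 measured adipocyte genes had a log2 fold change below 0. Without knockout 2, 3 adipocyte genes fell (camera adjusted p of the list 3.14e-04), without control 1, 1 adipocyte gene fell (0.00631), and without control 2, 1 erythroid gene fell.

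Over the 29 lists, 7 were higher and 7 lower in the knockout at the preset correlation, and 0 passed with an estimated correlation, where 6 had an unadjusted p under 0.05. The permutation test of list levels put 10 lists at its smallest exact p of 0.0286 and 0 past the threshold after adjustment, and fry passed 8. Other splits of the 8 libraries gave up to 17 lists at the preset correlation, in a split that exchanged a single control for a single knockout. Splits with as many controls as knockouts on each side gave at most 13.

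**Figure D4:**
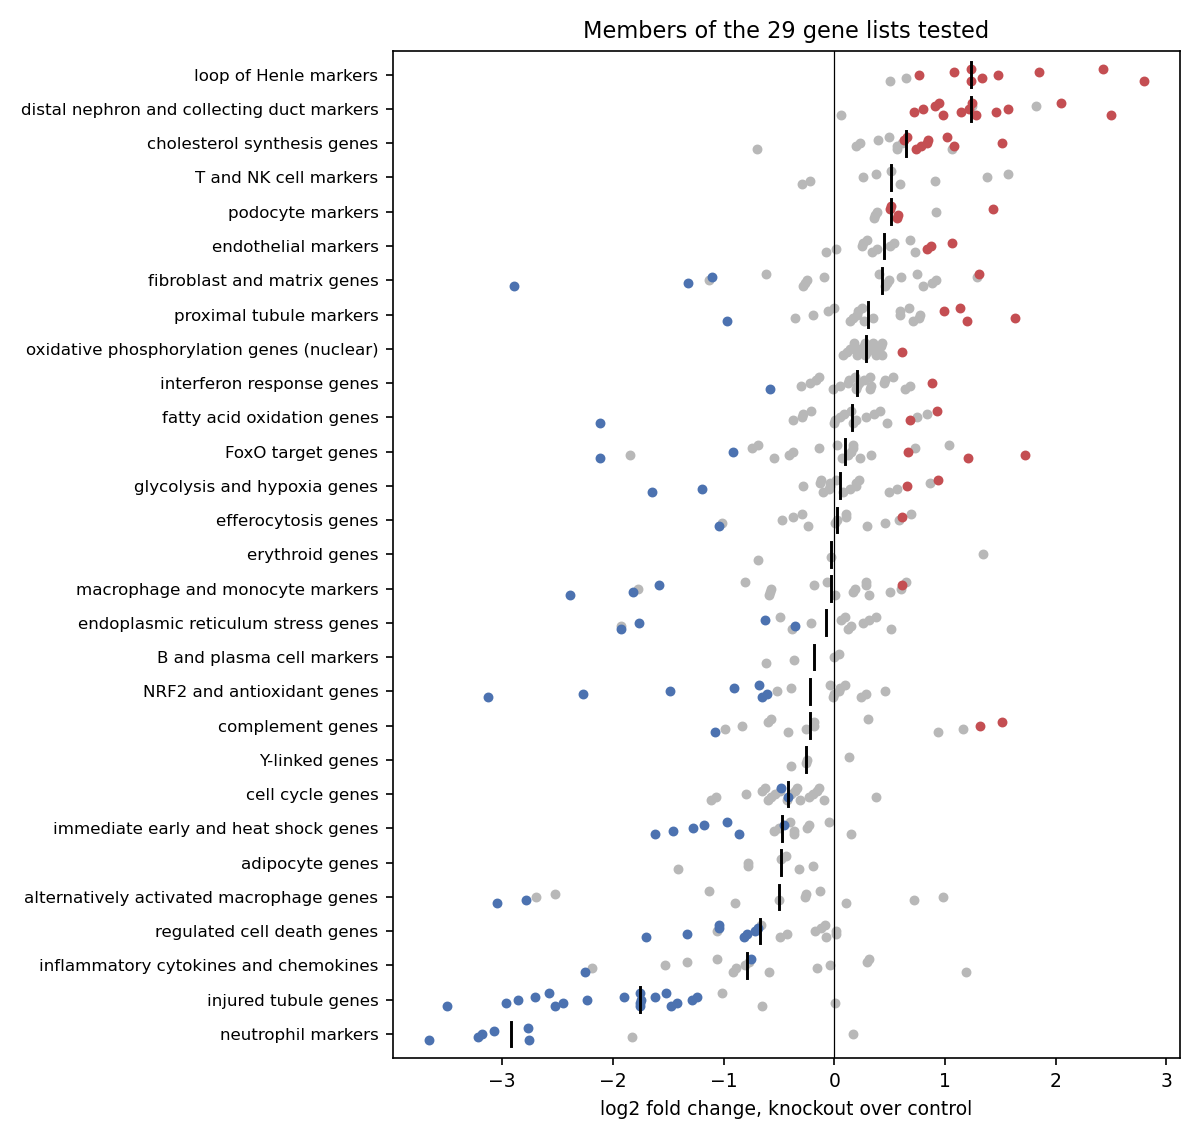
Log2 fold change (knockout over control) of the measured members of the 29 gene lists tested, 1 point per gene, red and blue where the gene rose or fell at an edgeR adjusted p under 0.05 and grey otherwise, with a black bar at the list's median. Injured tubule genes have a median of -1.76, and the loop of Henle and distal lists have medians of 1.24 and 1.23.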

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

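The tests of fewer macrophages and of reads assigned to Lyz1 were chosen only after the levels had been seen, and the test of an insertion before.

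In knockout 3 the Lyz2 level was -1.23 on the log2 CPM scale, against 4.67 to 5.55 in the other 3 knockouts. Control 1 was also low, at 1.22, against 4.78 to 5.66 in the other controls, a gap that did not pass the same test for single distant values. The tables argue against fewer macrophages: the other 18 macrophage and monocyte markers were 0.75 above the mean of the other 6 libraries in control 1 and at -0.22 from it in knockout 3, while Lyz2 differed by -3.84 and -6.29. They also argue against reads assigned to Lyz1, since the sum of both genes in control 1 reached 0.284 of the lowest sum of the other 6 libraries, and in knockout 3 0.0735. An insertion in both copies of Lyz2 in those animals stays open: 0 other genes were at least 8-fold lower in both libraries than in each of the other 6, but no other pair of libraries had more than 1 such gene, so this count could not have spoken against it. Control 1 is labelled wild type and lies with the controls on the first principal component.

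Single libraries stood far from the other 3 of their group in 11 more values, all in log2 CPM. In control 1, Il1b was at 3.33 (others 1.53 to 1.80), Cxcr2 at 3.48 (1.02 to 1.09), Atp5a1 at 10.4 (10.9 in the others), Nsdhl at 5.09 (5.76 to 5.78) and the mean of the fatty acid oxidation genes at 7.14 (7.81 to 7.94). In control 3, Kdr was at 3.99 (5.00 to 5.06) and the mean of the fibroblast and matrix genes at 4.30 (4.85 to 4.93). In the knockouts, Uroc1 was at 6.53 in knockout 3 (7.05 to 7.14), Slc26a4 at 6.32 in knockout 4 (6.48 to 6.51), the mean of the neutrophil markers at 0.356 in knockout 1 (-0.45 to -0.40) and the mean of the adipocyte genes at 4.13 in knockout 2 (0.79 to 1.27). The 12 values came from 206 groups of 4 tested, in which chance at 1 in 20 gives 10.3.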

How the results depend on the processing

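Leaving out control 1 and knockout 3, leaving out control 2 and knockout 2, leaving out Rn45s and removing length and GC trends were chosen after the data were seen; the other settings were planned.

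Against 1909 changed genes (967 higher, 942 lower), DESeq2 called 3009 (1574, 1435), a surrogate variable 3423 (1749, 1674), an adjusted p under 0.1 3114 (1553, 1561) and the test beyond 1.5-fold 276 (143, 133). Without control 1 and knockout 3 the counts were 1045 (549, 496) and without control 2 and knockout 2 1008 (538, 470). Lower genes numbered 1447 with sample quality weights and 1665 with length and GC trends removed, which were known for 98.4% of tested genes. Leaving out 1 library gave 907 to 1984 (457 to 1001 higher, 450 to 983 lower). For these moves the cause was not tested. The Foxo1 log2 fold change of 0.29 passed in DESeq2 (0.29), with quality weights (0.29), with a surrogate variable (0.29) and at 0.1 (0.29). Of 63 named genes past the threshold, 46 stayed past it in all 8 fits without 1 library.

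With the replicate number as a block, 865 genes changed (447 higher, 418 lower), and 49 of the 63 named genes passed. The block used the numbers in the sample titles, and the labels do not say what a number shares. By title, same-numbered libraries had correlations of -0.20, 0.04, 0.15 and -0.16, and 0 of 8 libraries correlated best with their own number. The sample descriptions and the table columns number the knockouts differently, and by those the groups share 2 numbers, which join control 2 with knockout 1 (0.35) and control 3 with knockout 2 (0.17), each the best match of both. These are hints from the data, not the design, and no block was fitted on them, so whether some libraries are paired stays open.

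Against 7 lists higher and 7 lower, an estimated correlation gave 0 and 0, fry 4 and 4 and the exact permutation test 0 and 0. Medians near 0 turned sign, and the cause was not tested. Leaving out 1 library gave ranges of -0.69 to 0.26 (Lyz2), -0.24 to 0.25 (macrophage), -0.76 to 0.35 (B cell), -0.060 to 0.13 (efferocytosis), -0.10 to 0.15 (FoxO targets), -0.21 to 0.053 (endoplasmic reticulum stress) and -0.64 to 0.069 (erythroid). Without control 2 and knockout 2, Lyz2 was at 0.24, macrophage at 0.21 and B cell at 0.24; without control 1 and knockout 3, macrophage was at 0.22, fatty acid oxidation at -0.038 and erythroid at 0.18. With trends removed, efferocytosis was at -0.085, glycolysis at -0.030, FoxO targets at -0.0093 and erythroid at 0.029. The B cell median was 0.0029 with a CPM filter. Among lists, the setting without control 2 and knockout 2 lost the cell cycle call (-0.16, camera adjusted p = 0.109) and gained interferon (0.55, 4.99e-04), T and NK cell (0.87, 0.0118) and adipocyte genes (-1.45, 0.00451). Without control 1 and knockout 3, the proximal call was lost (0.10, 0.246), and alternatively activated macrophage (-0.52, 0.0436) and adipocyte genes (-0.62, 0.0186) were gained. These same lists were gained with no low-count filter (-0.80, 0.0315 and -0.78, 0.00887) and with the replicate block (-0.47, 0.0432 and -1.08, 0.00965), and the first of them with library totals alone (-0.49, 0.0473). The NRF2 call was lost with trends removed (-0.24, 0.0542). Leaving out mitochondrial and haemoglobin genes removes no tested gene and was not run. At this depth and spread, the simulation with 200 changed genes recovered 8.96% of 1.5-fold changes. The adjusted threshold is less strict where more genes change, as with the 1909 called here, so recovery in these data may differ.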

Other observations

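The tests of the Slc family, of length and GC content, of even dilution, of all leukocytes and of a single control library were chosen only after the results had been seen, and the tests of splits, of severity and of neighbouring genes before.

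Genes of the solute carrier (Slc) families, which encode most membrane transporters of small molecules, rose more often than other genes. Of 311 tested, 49 rose and 17 fell, against 6.45% of all tested genes that rose and 6.28% that fell. For the rise, a one-sided Fisher's exact test gave an adjusted p = 1.76e-06 over 360 tests of 180 symbol families. That test treats genes as independent, so its p does not measure the spread between libraries. The fructose transporter gene Slc2a5 rose from 22.4 to 128 CPM (log2 fold change 2.52, SE 0.45), Slc16a7 from 28.3 to 106 CPM and the sodium-calcium exchanger gene Slc8a1 from 28.4 to 111 CPM. Among those that fell were the phosphate transporter genes Slc34a2 (84.0 to 23.8 CPM, log2 fold change -1.82, SE 0.25) and Slc20a1 (log2 fold change -1.14). More of these genes rose than fell under each of the 24 other settings, with 31 risen and 7 fallen without knockout 4. The family overlaps with the loop of Henle and distal nephron lists, through Slc12a1, Slc12a3, Slc4a1 and Slc26a4. The levels of those lists differed by 1.45 and 1.31 between the same groups (log2, knockout minus control). It also overlaps with the proximal tubule list, among others through the risen Slc7a13 and Slc5a8. The level of that list differed by 0.46. The genes given as examples of the family were chosen after their values were seen. The symbol stem also takes in genes that are not transporters, and close paralogs such as the Slc22a genes may share reads.

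For the lower injured tubule genes and higher loop of Henle and distal markers of the knockout, the tables argue against a trend with gene length or GC content, since the injured tubule median was -1.83 once it was removed. They argue against an even dilution by injured tubule RNA in the controls as the whole cause of the loop of Henle rise. The loop of Henle change exceeded the proximal tubule change by 0.991 on the log2 scale, and the difference of both levels ran from -2.67 to -1.94 in controls and from -1.46 to -0.88 in knockouts. The proximal tubule, endothelial and podocyte levels differed by 0.46, 0.54 and 0.65 (log2, knockout minus control), so an even dilution stays open for those lists. Whether it adds a part to the loop of Henle and distal rise was not tested. A different severity of injury apart from the genotype stays open: the slope of each gene on the injured tubule level among the 4 controls correlated with its fold change, control over knockout, at 0.461 across 14978 genes, which are not independent. The slope among the 4 knockouts correlated with that fold change at -0.03. The injured tubule level varied little among the knockouts (SD 0.0846, against 0.402 in controls), so the value of -0.03 says little either way. Of 1890 called genes compared, 75.0% changed in the direction given by the slope among the controls. The controls enter both sides of this share and of the value of 0.461, so both are weak evidence. The injured tubule level was at least 7.11 in controls and at most 5.72 in knockouts, so severity and genotype cannot be told apart. With that level as a covariate 0 genes changed, but a covariate that separates the groups takes up their difference, so this fit cannot decide either.

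Neutrophil markers were lower in the knockout. A lower level of all leukocyte RNA is argued against by the neutrophil change minus the macrophage change of -1.78 on the log2 scale (exact permutation p = 0.0286, the smallest possible). A single control library with many neutrophil reads is argued against by a median of -1.85 without control 1. A milder injury in the knockout animals, as weighed for the tubule genes, may also lower these markers and was not tested for them.

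Strain variants carried along with the engineered alleles could add changed genes near them. Among the 100 nearest tested genes of Foxo1 10 changed, against 12.8% of the rest (two-sided Fisher's exact p = 0.546), and among those of Lyz2 15 changed, against 12.7% (Fisher's exact p = 0.455), so no excess was found. Gene order came from the GRCm38.p6 annotation.

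Among all 35 splits of the 8 libraries into 4 and 4, 1 gave as many changed genes as the real one, which was the real one itself (1909; the highest other split gave 0). That share of 0.0286 is the smallest this design can give. At the 0.05 level it argues against chance for the count of genes, provided that the libraries are independent, which no label states. It does not tell the genotype from any other difference between the groups. For the lists, 6 of 35 splits gave at least the 14 of the real split and the highest other gave 17. Each of the other splits that reached 14 exchanged a single control for a single knockout, so it kept much of the real group difference. Splits with as many controls as knockouts on each side gave 4 to 13 lists. The share of 6 in 35 therefore cannot decide whether chance gives as many lists. Chance is not excluded for the count of lists at the preset correlation.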
